A study of Mus musculus with 9 samples.

How the data were processed

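Poly(A) RNA libraries from 9 tissue samples labelled ventral hippocampus were prepared with dUTP second-strand marking and sequenced as 150 nt paired reads, per the labels' protocols. The authors deposited a table of raw gene counts and a table of FPKM values, both with 1 column per library. HISAT2 2.2.1, StringTie 2.1.6, cutadapt 1.9 and the GRCm39 mouse genome are named in the submitters' processing notes, without their roles. The annotation release, the strand setting, the treatment of reads with several alignments and the program that wrote the counts are not given in the sources used here. Because strand use was not stated, reads of a gene and of an overlapping antisense gene cannot be told apart.

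The deposited count table held 57132 gene IDs, of which 35052 had a count in any library. Gene symbols came from the GENCODE M21 annotation, which named 51880 of the IDs, holding 99.7% of the counts. That annotation is of GRCm38, a different build from the authors', so it served for names only and no coordinates are given. The FPKM values, deposited by the authors, were the counts rescaled: a gene's FPKM per share of the counts was constant between libraries within 0.974 to 1.018 over 11827 genes with at least 200 counts. They are not independent evidence and entered as an alternative only. No library pair of a group agreed within sampling noise by a chi-square test of its counts.

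Groups came from the sample labels. Counts were analysed in R 4.3.3 with the edgeR 4.0.16 quasi-likelihood test, with all 9 libraries in 1 fit, a mean per group, TMM scaling and edgeR's default filter on expression, which left 22501 genes. Each group's spread was pooled in that fit. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. Comparisons were SI-SC against GL-SC, SI-Nr3c1 against SI-SC, and SI-Nr3c1 against GL-SC. CPM values used TMM-scaled library sizes. A gene at 0 in every library of a group was given a floor of 3 counts per library, equal to 0.0478 CPM in GL-SC, 0.0503 in SI-SC and 0.0455 in SI-Nr3c1; floors cover counting error only, since reads carry no molecular identifiers. Each bound on a fold set the mean of the other group against this floor. Between TMM and RLE scaling the median log2 fold change of all genes moved by -0.012 at most.

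The design, the tests, the named-gene rule, 20 gene lists and 19 cell type marker lists were fixed before the data were examined. The lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, under which 0 lists passed in the isolation and 0 in the knockdown comparison, and with fry. The lists covered iron handling, ferroptosis, Parkinson disease genes, glucocorticoid response and signalling, immediate early genes, synapses, transmitter receptors, mitochondria, autophagy, heat shock, inflammation, cholesterol synthesis, clock, plasticity, ion channels, ribosomes, hippocampal and other neuron types, glia, vessels, meninges, choroid plexus, ependyma and blood cells. For 5 list symbols no ID matched. Another 6 lists (cerebellar granule and Purkinje neurons, hindbrain patterning factors, brainstem transmitter neurons, telencephalic neurons, immunoglobulins) were written after the data were seen. A region score was the mean log2 CPM of the telencephalic list minus that of both cerebellar lists.

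The named-gene rule took a fixed set of genes, of which 15 are reported, the 10 largest changes per direction among genes past the threshold with a mean of at least 1 CPM, a symbol that is not a predicted-gene name and no overlap between groups, the 10 leading genes called in opposite directions, and up to 4 members per list with the smallest p. Some genes of the rule are not reported here. Members of the region lists were named after their values were seen.

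On simulated data with the real means, totals and dispersions, edgeR on 21736 genes recovered 26 of 100 genes changed 2-fold and 65 of 100 changed 4-fold in the isolation comparison, and 32 and 67 of 100 in the knockdown comparison, calling 2 and 1 unchanged genes. Those changes were planted in SI-SC. In these and the further simulations, changes were planted only in genes with a mean above 1 CPM. In a separate simulation, added after the data were seen, changes were planted in SI-Nr3c1, and of 21731 genes tested against GL-SC edgeR recovered 35 of 100 changed 2-fold and 84 of 100 changed 4-fold, calling 3 unchanged genes. Camera called a list of 30 genes shifted 1.5-fold and 0 of 20 unchanged lists. The simulated genes varied independently and the unchanged lists were random genes, so this does not test camera on lists whose members move together. Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom, no filter, a stricter filter, fits of only the compared groups, a replicate block, limma on log2(FPKM + 0.1) and log2(FPKM + 1), other thresholds and each library left out. A region score as a covariate and libraries thinned to 1 total were added after the data were seen.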

Results

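RNA sequencing measured transcript levels in tissue labelled ventral hippocampus, the part of the hippocampal formation tied to anxiety behaviour, from male Camk2a-Cre mice on a C57BL/6 background. Camk2a-Cre drives Cre recombinase in excitatory forebrain neurons, and the injected AAV5 vectors carried a Cre-dependent short hairpin RNA. The 9 libraries formed 3 groups of 3. Group-housed mice, kept 5 per cage, received a scramble hairpin (GL-SC). Mice isolated 1 per cage received the scramble hairpin (SI-SC) or a hairpin against Nr3c1, the glucocorticoid receptor gene (SI-Nr3c1). Housing lasted 28 days. The total counts of the libraries were 67121618, 62087978 and 59315807 in GL-SC, 66765623, 52696165 and 65722675 in SI-SC, and 67677194, 65259448 and 61110666 in SI-Nr3c1. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. The labels give the virus a titre of 200.0 vg/mL in the group-housed mice and 2.00E+12 vg/mL in both isolated groups, and whether the lower value is a typing error is not known. Every difference between GL-SC and an isolated group is therefore confounded with the labelled titre.

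Nr3c1 (ENSMUSG00000024431), the target of the hairpin, was measured at 59.8, 81.6 and 85.3 CPM, the count scaled to a fixed library total, in the GL-SC libraries, 55.0, 54.6 and 59.3 in SI-SC, and 55.2, 76.6 and 57.5 in SI-Nr3c1. The group means were 75.5 ± 13.8, 56.3 ± 2.62 and 63.1 ± 11.8 CPM (SD, n = 3). Nr3c1 was therefore not lower in the libraries labelled SI-Nr3c1 than in SI-SC: the log2 fold change was 0.16 (SE 0.17, edgeR adjusted p = 0.544). Against GL-SC it was -0.26 (SE 0.17, edgeR adjusted p = 1). The difference between SI-SC and GL-SC, a log2 fold change of -0.42 (SE 0.17), did not pass the threshold either (edgeR adjusted p = 0.117). With a region score as a covariate, added after the data were seen, the difference between SI-Nr3c1 and SI-SC turned to -0.81 (SE 0.31), which did not pass. The tissue level also holds Nr3c1 from cells without Cre. The group name is used below as the label gives it, and every direction drawn from libraries labelled SI-Nr3c1 carries this limit.

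**Figure D1:**
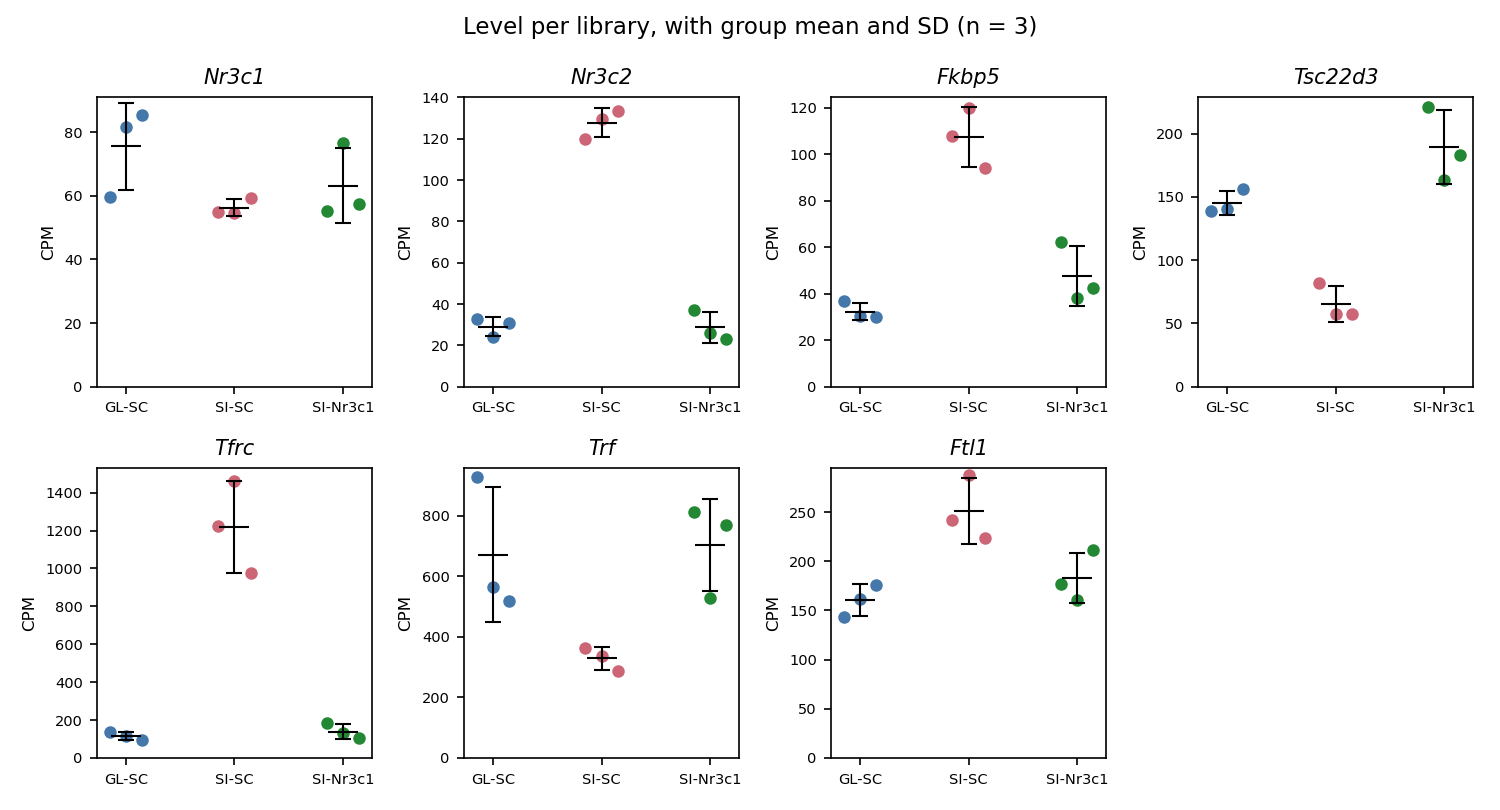
Levels in CPM (y axes, linear, from 0) of 7 genes in each of the 9 libraries, by group, with points for libraries and bars for the group mean and SD (n = 3). Tfrc was 1220 ± 243 CPM in SI-SC and 117 ± 21.7 in GL-SC, while Nr3c1 was 56.3 ± 2.62 in SI-SC and 63.1 ± 11.8 in SI-Nr3c1.

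The first comparison, SI-SC against GL-SC, asked how isolated and group-housed mice differed under the control hairpin. Iron handling is named in the study's title. Housing was not separable from the labelled titre, nor from region content. The region score, built from lists written after the data were seen, was 3.59 to 4.63 in SI-SC and -7.18 to -1.34 in GL-SC. Tfrc (ENSMUSG00000022797), the transferrin receptor that takes up iron, rose in SI-SC to 1220 ± 243 from 117 ± 21.7 CPM (log2 fold change 3.38, SE 0.26, edgeR adjusted p = 0.000229, n = 3). Nr3c2, the mineralocorticoid receptor gene, rose by 2.13 (SE 0.20), and Fkbp5, a glucocorticoid-induced co-chaperone of the receptor, by 1.73 (SE 0.20) on the log2 scale. Trf, encoding transferrin, fell by 1.03 (SE 0.24), and Tsc22d3, a glucocorticoid-induced regulator also called GILZ, fell by 1.15 (SE 0.17). Trf is also a member of the mature oligodendrocyte and myelin list, whose median log2 fold change was -0.95. Of the 15 genes fixed in advance and reported here, 6 passed the threshold, including Ftl1, the ferritin light chain (0.65, SE 0.14, edgeR adjusted p = 0.0155), each with the 3 SI-SC libraries all on 1 side of the 3 GL-SC libraries, which adds no support since the genes were called on these libraries. Trf no longer passed without SI-SC replicate 1 (-1.10), 2 (-1.05) or 3 (-0.94), and Ftl1 no longer passed without GL-SC replicate 2 (0.65) or SI-SC replicate 2 (0.54). Those that did not pass were Nr3c1, Sncb, Slc11a2, Slc40a1, Fth1, Ireb2, Aco1, Sgk1 and Per1. Their log2 fold changes lay between -0.56 for Slc40a1, the iron exporter, and 0.56 for Fth1, the ferritin heavy chain. Ferritin genes have processed pseudogenes whose reads the counting could have split, so their values are uncertain.

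Members of the iron list lay on both sides. Of 34 iron uptake, storage and export genes tested, 7 were higher, 3 lower and 24 did not pass (camera adjusted p = 0.855; 7 and 3 when adjusted over the list alone), with a median log2 fold change of -0.02 against a mean of 0.53. Among the lower members was Steap2, a metalloreductase (14.1 against 81.5 CPM). The Parkinson disease list had 2 of 23 higher, with Synj1, a synaptic vesicle phosphatase, among them, and 1 lower (camera adjusted p = 0.997; 2 and 1 when adjusted over the list alone). The glucocorticoid receptor responsive list had 6 higher, among them Cebpd, a transcription factor (log2 fold change 2.28), and 2 lower of 30 (camera adjusted p = 0.855; 7 and 2 when adjusted over the list alone), with a median of -0.14 against a mean of 0.26. For the corticosteroid and CRH signalling list these counts were 4, 3 and 21 tested (7 and 5 when adjusted over the list alone), with Hsd11b1, which regenerates active glucocorticoid, lower by a log2 fold change of -1.37. The ferroptosis list had 3 higher and 3 lower of 29 (3 and 3 when adjusted over the list alone), with a median of -0.09 against a mean of 0.21. In the same libraries the cerebellar granule neuron list, written after the data were seen, had a median log2 fold change of -3.72 with 11 of 16 members lower.

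Markers of hippocampal neurons were higher in SI-SC for 3 of the 4 lists tested. In the dentate granule neuron list 10 of 16 members rose and 2 fell (12 and 2 when adjusted over the list alone), with a median log2 fold change of 1.67, for example Lct (log2 fold change 6.34) and Trpc6 (17.6 against 1.26 CPM). The list passed camera (adjusted p = 7.57e-06) but not with an estimated correlation (adjusted p = 0.0775 with an estimated correlation). In the CA1 and subiculum list 8 of 16 rose (10 and 1 when adjusted over the list alone; camera adjusted p = 3.98e-06, adjusted p = 0.548 with an estimated correlation), among them Gpr161, Man1a and Tle1 with log2 fold changes of 2.64, 1.61 and 1.27. In the ventral pole list 7 of 15 rose (9 and 1 when adjusted over the list alone; camera adjusted p = 0.000305, adjusted p = 0.548 with an estimated correlation), including Plk2 (2.69). The CA3 and CA2 list had 6 higher and 2 lower of 17 (7 and 3 when adjusted over the list alone) and did not pass (camera adjusted p = 0.287), with Bok at 2.15 and Grik4 at 1.82. The glutamatergic synapse list had 23 higher and 5 lower of 41 (23 and 6 when adjusted over the list alone; camera adjusted p = 0.000161, adjusted p = 0.451 with an estimated correlation), for example Dlg3 (1.26), the NMDA receptor subunit Grin2a (1.91) and Nptxr (1.96). The immediate early genes had 13 higher and 1 lower of 30 (16 and 2 when adjusted over the list alone; camera adjusted p = 0.000272, adjusted p = 0.548 with an estimated correlation), including Junb (2.19), Arc (1.96) and Ptgs2 (27.1 against 0.957 CPM).

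These neuronal groups moved together with markers of other brain regions. The 6 lists written after the data were seen included telencephalic pyramidal and cortical neurons, of which 13 of 20 were higher in SI-SC (median log2 fold change 3.61; Camk2a 3548 against 268 CPM, Neurod6 118 against 8.63 CPM). Purkinje neuron markers were lower for 16 of 18 (median -3.65; Pcp2 0.439 against 176 CPM), midbrain and hindbrain patterning factors for 7 of 22, and brainstem transmitter neuron markers for 4 of 13. The median of the patterning factors was -8.39 as fitted and -5.72 with the 11 members at 0 in SI-SC placed at their bound. En1, a midbrain and hindbrain homeobox factor, was 0.0676 CPM in SI-SC and 7.00 in GL-SC. These lists were not independent of the data, and with an estimated correlation their adjusted p lay between 0.0613 and 0.239.

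**Figure D2:**
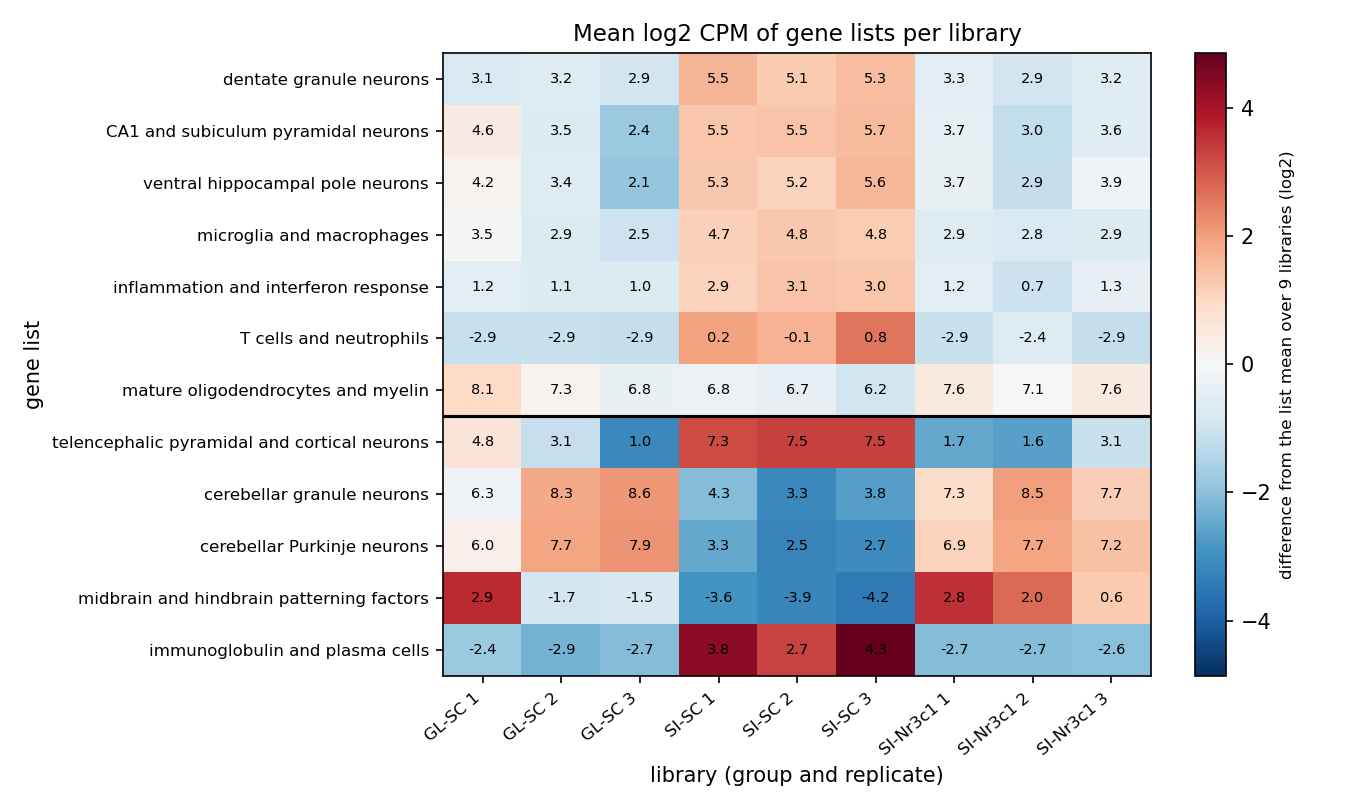
Mean log2 CPM of 12 gene lists (rows) in each of the 9 libraries (columns), with the colour giving the difference from the list's mean over the libraries. The lists under the line were written after the data were seen, and the telencephalic list lay between 7.35 and 7.52 in SI-SC and between 1.04 and 4.82 in the other 6 libraries.

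Immune transcripts were higher in SI-SC. Of 40 inflammation and interferon genes 25 rose and 0 fell (32 and 0 when adjusted over the list alone), with a median log2 fold change of 1.9 (camera adjusted p = 1.24e-13, adjusted p = 0.106 with an estimated correlation). B2m, the light chain of MHC class I, rose to 180 from 55.9 CPM, H2-K1 to 152 from 33.2 and Bst2 to 17.4 from 3.49. Of 20 microglia and macrophage markers 15 rose (18 when adjusted over the list alone; camera adjusted p = 1.47e-10, adjusted p = 0.451 with an estimated correlation), including the complement genes C1qa (89.6 against 14.4 CPM) and C1qb, and Tmem119 (37.8 against 9.96 CPM). Of 14 T cell and neutrophil markers 8 rose (11 when adjusted over the list alone; camera adjusted p = 1.82e-06, adjusted p = 0.0977 with an estimated correlation), with Ccl5 at 3.24 against 0.102 CPM. The median of this list was 4.04 as fitted and 3.75 with the 1 member at 0 in GL-SC at its bound. Immunoglobulin and plasma cell genes, a list written after the data were seen, had 11 of 14 members higher (13 and 1 lower when adjusted over the list alone), with a median of 6.41 as fitted and 6.30 with the 3 members at 0 at their bound. The telencephalic and cerebellar lists separated the same libraries as these immune transcripts.

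Glial and epithelial lists also moved by camera. The myelin, choroid plexus and ribosomal lists did not pass fry (fry adjusted p = 0.2, 0.18 and 0.104). Of 18 myelin genes 8 were lower and 0 higher (10 lower when adjusted over the list alone; camera adjusted p = 0.000272, adjusted p = 0.939 with an estimated correlation), for example Ugt8a (21.1 against 65.4 CPM) and Tspan2 (77.2 against 152 CPM). Choroid plexus markers were called higher (2 of 17 members, 6 when adjusted over the list alone; camera adjusted p = 0.0024, adjusted p = 0.939 with an estimated correlation), including Kl (66.6 against 12.3 CPM). Cytosolic ribosomal protein genes had 14 of 50 higher (23 when adjusted over the list alone; median 0.46, camera adjusted p = 1.64e-07, adjusted p = 0.939 with an estimated correlation); many have pseudogene copies. The astrocyte list had 2 higher and 5 lower of 16 (2 and 6 when adjusted over the list alone; camera adjusted p = 0.254), with Slc1a2, the glutamate transporter, at 2082 against 849 CPM and S100b at 54.9 against 231 CPM. GABAergic interneuron markers went both ways (5 higher and 4 lower of 20, 8 and 6 when adjusted over the list alone, camera adjusted p = 0.375). Cck was higher and Pvalb was 17.8 against 247 CPM. Pvalb is also a member of the Purkinje neuron list, of which 16 of 18 members were lower, so its fall cannot be assigned to interneurons. The same libraries differed in cerebellar granule markers, of which Cbln3 was 1.88 CPM in SI-SC and 896 in GL-SC.

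In all 28 of the 39 fixed lists did not pass camera, and those not yet described had adjusted p from 0.0542 for nuclear oxidative phosphorylation genes to 0.993 for striatal neurons. Among neuronal function lists, the members higher and lower were 11 and 8 of 39 for ion channels (14 and 9 when adjusted over the list alone), 7 and 7 of 33 for the presynaptic vesicle cycle (10 and 8), 5 and 8 of 24 for GABA-A receptors and the inhibitory synapse (6 and 9), 8 and 4 of 38 for dopamine, serotonin and acetylcholine genes (8 and 6), and 4 and 5 of 26 for neurotrophins and plasticity (4 and 6). Among lists of general cell function, the counts were 6 and 5 of 37 for autophagy and lysosome (9 and 5 when adjusted over the list alone), 3 and 1 of 29 for heat shock (3 and 1), 0 and 3 of 24 for cholesterol synthesis (0 and 2), 1 and 5 of 22 for the clock (1 and 6), 0 and 2 of 56 for nuclear oxidative phosphorylation (0 and 0) and 2 and 0 of 15 for mitochondrially encoded transcripts (2 and 0). Among markers of other neurons, they were 1 and 5 of 19 for thalamus and habenula (1 and 5 when adjusted over the list alone), 2 and 2 of 16 for cortex and amygdala (2 and 4) and 1 and 1 of 14 for striatum (1 and 1). Among other cells, they were 1 and 1 of 16 for endothelium (1 and 1 when adjusted over the list alone), 1 and 1 of 14 for pericytes (1 and 1), 2 and 1 of 17 for fibroblasts (2 and 1), 0 and 1 of 12 for ependyma (0 and 1), 0 and 3 of 12 for oligodendrocyte precursors (0 and 3) and 1 and 0 of 8 for erythrocytes (1 and 0). The median and the mean differed in sign for GABA-A receptors, heat shock, neurotrophins, cortex and amygdala, striatum, fibroblasts and ependyma.

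The genes with the largest changes were immunoglobulin genes on the higher side. Ighg2b, Ighg1, Ighg3, Igkv4-53, Ighv1-26, Igkv12-44, Igkv6-25, Igkv1-110, Igkv6-23 and Igkv6-15 had 0 counts in every GL-SC library. Against a floor of 3 counts per library they were at least 200-fold (Igkv6-15) to at least 2550-fold (Ighg2b) higher in SI-SC. Ighg2b was 122 ± 57.2 CPM in SI-SC. Immunoglobulin genes share near-identical segments, so single members are uncertain. On the lower side Ppp1r17, a Purkinje neuron protein, Skor2, Sycp1, Lbx1, Smpx, Pax8 and Calcr had 0 counts in every SI-SC library. By group mean they were at least 41.2-fold (Calcr) to at least 2390-fold (Ppp1r17) lower there. Single GL-SC libraries can lie far below the mean, as Calcr was 2.07 ± 2.53 CPM and Pax8 2.88 ± 4.66 CPM in GL-SC. Gabra6, a GABA-A receptor subunit of cerebellar granule cells, was 0.318 ± 0.251 CPM in SI-SC and 350 ± 261 in GL-SC. Cnpy1 was 0.332 against 325 CPM and Chil5 0.00508 against 4.69 CPM.

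Of 22501 genes tested with edgeR, 2272 were higher and 1925 lower in SI-SC, and 1491 and 1066 of these changed at least 2-fold. The counts depended on the libraries: without SI-SC replicate 1 they were 1441 and 1176, without SI-SC replicate 2 1385 and 1005, without SI-SC replicate 3 1181 and 920, without GL-SC replicate 2 1189 and 985, without GL-SC replicate 3 1509 higher, and without GL-SC replicate 1 2971 lower. With a region score added after the data were seen as a covariate, 482 were higher and 766 lower, and Fkbp5 (1.25), Tsc22d3 (-0.89) and Ftl1 (0.78) no longer passed.

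The second comparison, SI-Nr3c1 against SI-SC, asked what the Nr3c1 hairpin changed within isolated mice. The hairpin was not separable from region content there. The region score was -6.5 to -4.29 in SI-Nr3c1 and 3.59 to 4.63 in SI-SC. The libraries labelled SI-Nr3c1 had lower Tfrc (139 ± 41.3 against 1220 ± 243 CPM, log2 fold change -3.14, SE 0.26, edgeR adjusted p = 0.000217, n = 3). Nr3c2 was lower by -2.16 (SE 0.20) and Fkbp5 by -1.17 (SE 0.19), while Trf was higher by 1.10 (SE 0.24), Tsc22d3 by 1.53 (SE 0.17) and the clock gene Per1 by 0.73 (SE 0.22, edgeR adjusted p = 0.047). Trf no longer passed without SI-SC replicate 2 (1.11) or 3 (1.01) or SI-Nr3c1 replicate 1 (0.98). The myelin list, which also holds Trf, had a median log2 fold change of 0.85. Per1 no longer passed without SI-SC replicate 1 (0.76), 2 (0.74) or 3 (0.69), SI-Nr3c1 replicate 1 (0.57) or 3 (0.74), nor with limma-voom (0.71), no filter (0.77) or a replicate block (0.73). With the region score as a covariate Tfrc (-2.49), Fkbp5 (-0.64), Tsc22d3 (1.24) and Per1 (-0.22) did not pass. Per1 was past the threshold in this comparison and not in the first, where it was lower by -0.47; the difference between the comparisons was not tested. Of the 15 genes fixed in advance and reported here 6 passed. Ftl1 did not (-0.46, SE 0.14, edgeR adjusted p = 0.053), nor did Nr3c1, Sncb, Slc11a2, Slc40a1, Fth1, Ireb2, Aco1 or Sgk1, which lay between -0.13 for Fth1 and 0.69 for Sgk1. In the iron list 2 members were higher and 5 lower of 34 (camera adjusted p = 0.948; 5 and 8 when adjusted over the list alone). In these libraries the cerebellar granule list was higher (median log2 fold change 3.64, 11 of 16 members; adjusted p = 0.186 with an estimated correlation).

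Markers of hippocampal neurons were lower in the libraries labelled SI-Nr3c1 for 3 of the 4 lists tested. The CA3 and CA2 list did not pass, with 6 lower and 2 higher of 17 (8 and 4 when adjusted over the list alone; camera adjusted p = 0.193). For the lists that passed, the counts were 12 lower and 2 higher of 16 for dentate granule neurons (12 and 2 when adjusted over the list alone; camera adjusted p = 1.86e-05, adjusted p = 0.0937 with an estimated correlation), 12 lower of 16 for CA1 and subiculum (12 and 1 higher when adjusted over the list alone; camera adjusted p = 5.38e-06, adjusted p = 0.581 with an estimated correlation) and 8 lower of 15 for the ventral pole (9 and 1 higher when adjusted over the list alone; camera adjusted p = 0.000901, adjusted p = 0.646 with an estimated correlation). The telencephalic list had 18 of 20 lower (median -4.56) and the Purkinje list 15 of 18 higher (median 3.65), as lists written after the data were seen. Of the others of that kind, patterning factors had 9 of 22 higher (median 8.94, 6.19 with bounds), brainstem transmitter markers 4 of 13 higher (4.45, 4.38 with bounds) and immunoglobulin genes 12 of 14 lower (-9.75, -6.60 with bounds). None of the 6 lists of that kind, cerebellar granule neurons included, passed with an estimated correlation, where their adjusted p lay between 0.0693 and 0.186. The glutamatergic synapse list had 23 lower and 4 higher of 41 (24 and 5 when adjusted over the list alone; camera adjusted p = 1.24e-05, adjusted p = 0.28 with an estimated correlation), and the immediate early genes 13 lower and 2 higher of 30 (19 and 5 when adjusted over the list alone; camera adjusted p = 0.000181, adjusted p = 0.581 with an estimated correlation). Arc was 22.6 against 107 CPM. Immune lists were lower: 25 of 40 inflammation and interferon genes (30 when adjusted over the list alone; median -1.89, camera adjusted p = 2.03e-13, adjusted p = 0.11 with an estimated correlation), 17 of 20 microglial markers (18 when adjusted over the list alone; median -2.16, camera adjusted p = 2.4e-11, adjusted p = 0.4 with an estimated correlation) and 6 of 14 T cell and neutrophil markers (12 when adjusted over the list alone; camera adjusted p = 1.86e-05, adjusted p = 0.11 with an estimated correlation). The T cell marker Ms4a4b had 0 counts in SI-Nr3c1 and was at least 33.6-fold lower. Myelin genes were higher (5 of 18, 5 when adjusted over the list alone; camera adjusted p = 0.000278, adjusted p = 0.811 with an estimated correlation), as were nuclear oxidative phosphorylation genes (14 of 56, 14 when adjusted over the list alone; median 0.24, camera adjusted p = 0.000181, adjusted p = 0.864 with an estimated correlation; Cyc1 0.40 and Sdhc 0.43). Endothelial markers were lower for 6 of 16 (7 when adjusted over the list alone; camera adjusted p = 0.0313, adjusted p = 0.581 with an estimated correlation), including Ly6a, Eng and Flt1 with log2 fold changes of -1.09, -0.88 and -0.43. Ribosomal protein genes were lower for 3 of 50 (0 when adjusted over the list alone; camera adjusted p = 0.00173, adjusted p = 0.914 with an estimated correlation). The 27 other fixed lists did not pass, with camera adjusted p from 0.135 for the clock to 0.97.

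Among genes with the largest changes, Ppp1r17, Skor2, Lbx1, Sycp1, Pax8, Smpx, Gabra6, Cnpy1 and Calcr were higher in the libraries labelled SI-Nr3c1. Ppp1r17, with 0 counts in SI-SC, was at least 2280-fold higher. Fezf2, a deep-layer cortical neuron factor, had 0 counts in SI-Nr3c1 and was at least 1100-fold lower. Ighg1, Ighg3, Igha, Igkv4-53, Ighv1-26, Igkv12-44, Igkv6-25 and Igkv1-110 were also lower, with Igha at 307 ± 314 CPM in SI-SC and 0.0313 in SI-Nr3c1. In all, 2110 genes were higher and 2567 lower (edgeR). With log2(FPKM + 0.1) in place of counts the split was 2509 higher and 1975 lower. That fit tested 14711 genes, where the count fit tested 22501, so the gene set differed as well as the scale. In it the isolation split turned too, to 1944 higher and 2022 lower. Without SI-SC replicate 1 the counts were 1287 and 1708, without SI-SC replicate 2 1126 and 1694, without SI-SC replicate 3 1023 and 1482, and with the region score as a covariate, added after the data were seen, 968 and 716.

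The isolation and knockdown comparisons moved the same genes in opposite directions. Of the genes past the threshold in both, 3565 had opposite signs and 0 the same sign, which is 84.9% of the isolation calls. The 10 genes leading this set were Iqgap2 (97.8 CPM in SI-SC against 3.27 in GL-SC and 3.51 in SI-Nr3c1), Lmo7, Arhgap39, Prkca, Faah, Unc5a, Arhgef25, Ksr1 and Rapgefl1, which were highest in SI-SC, and S100b, an astrocyte calcium-binding protein, which was lowest there. Both comparisons use the same SI-SC libraries, so opposite signs arise by chance as well. With unchanged groups simulated around those libraries, 0 genes in any of 20 simulations were called in both with opposite signs. No group differed there, so almost no calls could arise and that 0 does not gauge the overlap. Independent lists would share 259 and 181 genes per direction where 1955 and 1610 were observed. The log2 fold changes of both comparisons add up to that of SI-Nr3c1 against GL-SC, where 0 genes passed. Opposite signs and a negative correlation therefore follow once SI-SC stands apart, and neither reference tests a reversal by the hairpin. Across 16277 genes with a mean of at least 1 CPM, which are not independent replicates, the correlation of the fold changes was -0.96 and the covariance -1.68, against -0.501 and -0.0749 in the simulations, a covariance difference of -1.60. The 3 SI-SC libraries could not be divided into separate controls for both comparisons, so part of the excess may come from the shared libraries. Without SI-SC replicate 1, 2 and 3 the overlap was 2288, 2112 and 1852 genes, without GL-SC replicate 2 it was 2068, and with the region score as a covariate 1155.

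**Figure D3:**
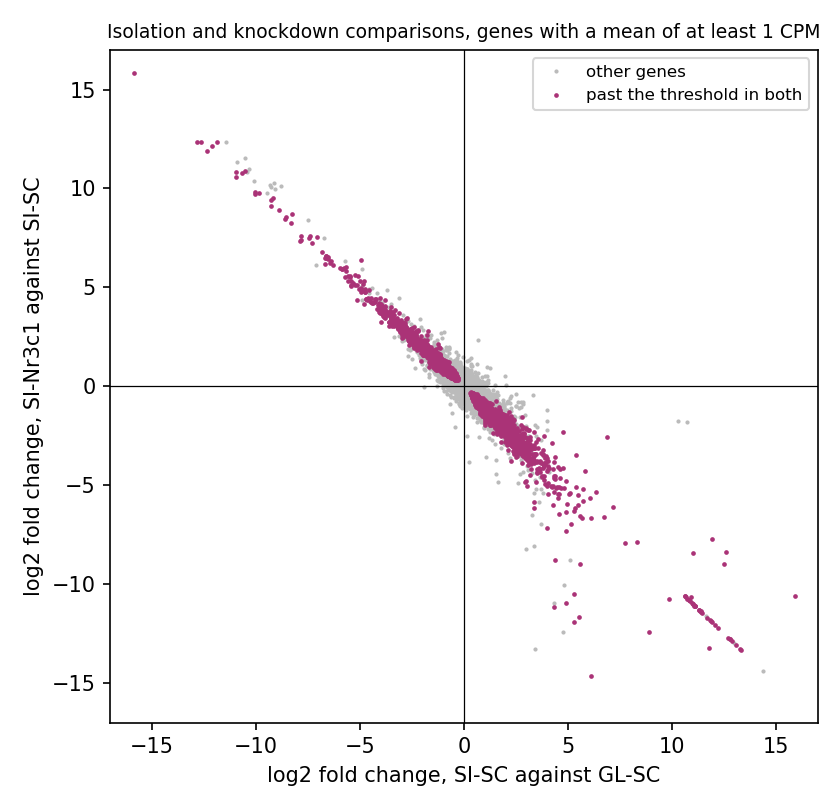
Log2 fold change of SI-SC against GL-SC (x axis) and of SI-Nr3c1 against SI-SC (y axis), 1 point per gene with a mean of at least 1 CPM, with genes past the threshold in both comparisons in purple. The points followed a falling diagonal, with a correlation of -0.96 across 16277 genes.

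The third comparison set SI-Nr3c1 against GL-SC, to see what remained of the difference from group housing; without a group-housed knockdown group, housing and hairpin could not be crossed. None of the 15 genes fixed in advance and reported here passed, with log2 fold changes between -0.54 (Slc40a1, SE 0.24) and 0.56 (Fkbp5, SE 0.19). Tfrc was 139 ± 41.3 against 117 ± 21.7 CPM (log2 fold change 0.25, SE 0.24). Across all genes edgeR called 0 higher and 0 lower at the adjusted threshold, with 715 at an unadjusted p under 0.05. On simulated data the same test recovered 35 of 100 genes changed 2-fold and 84 of 100 changed 4-fold in this comparison. Most 2-fold changes and some 4-fold changes could therefore go undetected, as could smaller ones. The planted changes were in genes with a mean above 1 CPM, so recovery at lower levels was not measured. The simulated genes also varied independently. Limma-voom also called 0, and DESeq2 called 10 higher and 12 lower. Endothelial markers were lower as a list (median -0.28, 0 of 16 members passing alone and 6 when adjusted over the list alone, camera adjusted p = 5.64e-10, adjusted p = 0.0948 with an estimated correlation), and so were pericyte and smooth muscle markers (median -0.31, 2 of 14 when adjusted over the list alone, camera adjusted p = 1.54e-05, adjusted p = 0.104 with an estimated correlation). Glucocorticoid receptor responsive genes were higher as a list (median 0.39, 1 of 30 when adjusted over the list alone, camera adjusted p = 7.41e-08, adjusted p = 0.498 with an estimated correlation). Ribosomal protein (median 0.20, adjusted p = 0.915 with an estimated correlation), oxidative phosphorylation (0.12, adjusted p = 0.972 with an estimated correlation) and choroid plexus genes (0.89, adjusted p = 0.817 with an estimated correlation) were higher as lists. Glutamatergic synapse (-0.15), GABA-A receptor (-0.13) and ion channel genes (-0.19) were lower as lists, each with adjusted p = 0.498 with an estimated correlation. The other 30 fixed lists did not pass. Of the lists written after the data were seen, patterning factors were higher (median 0.49) and telencephalic markers lower (-0.81), both with adjusted p = 0.884 with an estimated correlation. The libraries within these groups differed among themselves in region markers: the brainstem transmitter list lay at 4.80, 0.46 and 0.00 log2 CPM in GL-SC and at 4.25, 0.93 and 2.91 in SI-Nr3c1.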

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

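The region score and thinning settings were chosen after seeing the data. Counts of genes stayed within 1.5 times the reported values in the isolation and knockdown comparisons under RLE scaling, DESeq2, limma-voom, no filter, the stricter filter, fits of the compared groups alone, both FPKM scales, both other thresholds and thinning. Leaving out 1 library moved isolation between 1181 and 3276 genes higher and 920 and 2971 lower, knockdown between 1023 and 1548 higher and 1482 and 1927 lower, and their opposite overlap between 1852 and 4689; fewer libraries were then fitted. With the region score as a covariate, isolation gave 482 and 766, knockdown 968 and 716, and the overlap 1155, with Nr3c1 in knockdown reversed to -0.81 (SE 0.31, edgeR adjusted p = 0.141; 0.332 to 1 elsewhere); the score took values of 3.59 to 4.63 in SI-SC and -7.18 to -1.34 elsewhere, so it was nearly one with the groups. SI-Nr3c1 against GL-SC gave 10 and 12 genes with DESeq2 and 185 and 130 at unadjusted p with a 2-fold change; the cause was not tested. With an estimated correlation 0 lists passed in isolation and 0 in knockdown. With fry 10 lists passed in isolation, 8 of them also called by camera, and 15 in knockdown, 9 of them also called by camera. The CA3 and CA2 list and the astrocyte list passed fry, though not camera, in both comparisons. In isolation the myelin, choroid plexus and ribosomal lists passed camera and not fry. In knockdown the same held for the myelin, ribosomal and nuclear oxidative phosphorylation lists (fry adjusted p = 0.136, 0.269 and 0.122). Replicate numbers did not pair the samples: same-numbered deviations correlated between -0.20 and 0.33, and not every library correlated best with its own number. With a replicate block the isolation counts were 2074 and 1680, the knockdown counts 2001 and 2357, the overlap 3278, Nr3c1 0.15, and 11 and 13 lists passed.

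Reversals among named genes did not pass the threshold on either side unless stated, and their cause was not tested. With the region score, isolation values became 0.46 for Nr3c1, -0.84 for Fth1, 0.31 for Ireb2, 0.43 for Per1, -0.68 for Fezf2 and 0.08 for Flt1; knockdown values became 1.44 for Fth1, -0.41 for Ireb2 and -0.22 for Per1. Fezf2 in isolation and Per1 in knockdown had passed before. When single libraries were left out, values crossed 0 for Slc11a2 (-0.07 to 0.01), Sgk1 (-0.49 to 0.04) and Flt1 (-0.04 to 0) in isolation, for Slc40a1 (-0.11 to 0.16), Fth1 (-0.35 to 0.13) and Sncb (-0.01 to 0.16) in knockdown, and for Tfrc (-0.01 to 0.42) against GL-SC. Over all named genes and settings 203 results lost the threshold with their sign kept, 80 of them with the region score, and 22 gained it. Reversed results, Fezf2 and Per1 included, were counted apart from these. Genes under about 0.05 CPM could not be told from 0 at this depth.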

Other observations

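All tests of explanations in this part, and the 6 region and immunoglobulin lists, were chosen after the results were seen. The presynaptic vesicle and ion channel lists did not pass in isolation, while single members differed both ways. In the presynaptic list Syt2, a synaptotagmin of fast-firing hindbrain and inhibitory neurons, was 35.2 CPM in SI-SC against 496 in GL-SC, while Syt1 was 1147 against 454. Among ion channel genes Scn1a was lower in SI-SC (116 against 299 CPM). In the GABA-A receptor and inhibitory synapse list, which did not pass either, the receptor subunit Gabrb1 was 166 against 59.7 CPM and the vesicular GABA transporter Slc32a1 90.7 against 230. Aldoc, a glycolytic enzyme in both the astrocyte and the Purkinje neuron lists, was 962 against 1790 CPM.

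The opposite changes in the isolation and knockdown comparisons amounted to the SI-SC libraries standing apart from the other 6. A difference in depth was argued against, since 2273 genes were higher in isolation with all libraries thinned to the smallest total, 2199 of them also called higher at full depth. Markers of cerebellar neurons separated the libraries: the Purkinje list lay at 2.5 to 3.26 log2 CPM in SI-SC and at 6.03 to 7.94 elsewhere. The cerebellar granule list lay at 3.33 to 4.33 in SI-SC and at 6.3 to 8.55 elsewhere. For these markers the levels argue against 1 tissue makeup in all libraries. Among their members, Gabra6, Pcp2 and Cbln3 had means of 350, 176 and 896 CPM in GL-SC and 297, 160 and 912 in SI-Nr3c1. In SI-SC they were 0.318, 0.439 and 1.88 CPM. The levels of both lists thus argue against ventral hippocampus alone as the content of the GL-SC and SI-Nr3c1 libraries, which is how they are labelled. Different shares of forebrain and of cerebellum or hindbrain in the tissue pieces are a candidate explanation for the wider pattern. Over the 6 libraries outside SI-SC, the position on 3261 pattern genes outside every list followed the telencephalic list (Pearson r = 0.888, exact permutation p = 0.0181). The Spearman rho was 0.943 (exact permutation p = 0.0167), and both p-values were 0.0181 adjusted over 2 relations. Without the 2 libraries farthest from the median r was 0.413, so the relation rests on them. Among the 10 splits of the 6 GL-SC and SI-Nr3c1 libraries, the one setting GL-SC 1, SI-Nr3c1 1 and SI-Nr3c1 3 against the rest gave 2281 genes where the labelled split gave 0, which points to a structure of these samples other than their group. Effects of housing or hairpin on other genes within 1 tissue stay open, because the region score nearly coincides with the groups. With it as a covariate 482 genes were higher in isolation, of which 212 were also called higher without it.

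Nr3c1 was not lower in the libraries labelled SI-Nr3c1. Library makeup may hide a lower level in Cre-expressing neurons: with the region score as a covariate the log2 fold change was -0.81 (SE 0.31), which did not pass. Exchanged SI-SC and SI-Nr3c1 labels stay open too, since Nr3c1 differed by only 0.165 (SE 0.17) between them, and these explanations cannot be told apart because makeup is confounded with the groups. A weak effect of the hairpin in the tissue stays open, untested.

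Immunoglobulin transcripts were at 154 to 639 CPM for Igkc in SI-SC and at most 0.545 CPM in the other libraries. Blood in the tissue is argued against, since the 4 haemoglobin genes had a median log2 fold change of 0.65 with none passing, against 6.41 for the immunoglobulin list (6.30 with members at 0 at their bound). Choroid plexus as the source is argued against by 2 SI-Nr3c1 libraries, replicates 1 and 3, with choroid plexus levels of 3.73 and 4.0 log2 CPM, above the lowest SI-SC level of 3.47, and immunoglobulin levels of -2.71 and -2.62 against at least 2.69 in SI-SC. Isolation, the labelled titre and the injection were shared with SI-Nr3c1, whose immunoglobulin levels lay between -2.71 and -2.62, so none of these alone separates SI-SC from it. This does not set aside a local response to the injection. The telencephalic list lay at 1.56 to 3.12 log2 CPM in SI-Nr3c1 and at 7.35 to 7.52 in SI-SC. The SI-Nr3c1 libraries may therefore hold less of the injected tissue. A response to isolation that the hairpin altered, an immune response of other origin or a regional difference in immune cells may account for the pattern, and the tests did not separate them: the inflammation list had a median of 1.44 with the region score as a covariate, with 4 of 40 genes passing.

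With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In 2-group fits the isolation split gave 3859 genes and the highest other split 1, and the knockdown split gave 5790 and the highest other 1. For SI-Nr3c1 against GL-SC the labelled split gave 0 genes, so all 10 splits had to give as many or more and their share tells nothing. The highest gave 2281.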
